A study of Rattus norvegicus with 4 samples.

How the data were processed

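Array data on gene expression in rat skeletal muscle were re-analysed from the deposited scanner output. The samples were 2 arrays of sedentary wild-type (WT) Wistar rat muscle, 1 array of an exercised SPORTS rat and 1 array of a sedentary SPORTS rat. Groups were taken from the source names in the labels, which give the exercise state of the SPORTS arrays but not of the WT arrays. Per the labels' protocols, RNA was purified on silica columns, and 100 ng was amplified and labelled with Cy3 for one-colour hybridisation. Per the file headers, the scans were quantified with Agilent Feature Extraction 10.7.1.1, and all 4 arrays came from 1 slide. The deposited intensity values used were the processed signal, which per the file headers is background-subtracted and spatially detrended within each array, with no scaling between arrays. The median spot signal and the median local background, also intensity values per the file headers, were used for an alternative background correction, since no mean signal column was present in the files used.

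The authors' value table holds log2 values of the same arrays. Differences between its columns followed those of the log2 processed signal with r = 1 over 30015 probes, with an offset of at most 0.0032 per pair. Every row had a median of 0 over the 4 arrays. These checks fixed the scale (log2), the centring (on the median of each probe) and the direction of that table. Its column medians were 0.02 for WT array 1, -0.02 for WT array 2, 0.17 for the exercised and -0.15 for the sedentary SPORTS array. It served as an alternative source of values.

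Control spots and spots flagged as outliers were left out, and spots of one probe were averaged. Of 30367 probes, 352 had outlier flags on every spot of at least 1 array and were dropped. Values were log2 of the processed signal minus the array's 75th percentile. Probes were named by matching their accession, without version, to a RefSeq gene table of assembly GRCr8, which matched 59.4% of the 30015 probes used to 1 symbol. The array's design predates that assembly, so no coordinates are given. Where a gene had several probes, the probe with the highest mean over the 4 arrays was used. This left 26624 genes or unnamed accessions. A gene was tested if it was well above background, by the scanner software's flag, on at least 2 of the 4 arrays, which 13326 were, 8477 of them with a symbol. No probe used was saturated on any array.

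Linear models with moderated variances (limma 3.58.1, R 4.3.3) gave two-sided p-values, adjusted by the Benjamini-Hochberg method and called below 0.05. SPORTS against WT was fitted as 2 arrays against 2, with 2 residual degrees of freedom. A model with 3 groups gave sedentary SPORTS against WT, exercised SPORTS against WT, and exercised against sedentary SPORTS. Its spread came from the WT pair alone, with 1 residual degree of freedom, so the lone SPORTS arrays were assumed to vary like the WT pair. Genes at least 2-fold apart were counted for each pair of arrays. Genes for which both SPORTS arrays lay at least 2-fold to one side of both WT arrays were also counted, beside the other splits of the 4 arrays into pairs. A ± after a log2 difference is the standard error of the fit.

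A probe not well above background on any array of a group has only a bound there. Its difference is given as "at least N-fold": the mean of the brighter group against the mean, per array of the dimmer group, of the higher of the probe's own value and the array's lowest signal well above background. The adjusted p beside a bound is that of the fit to the measured values.

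Before the data were examined, 36 gene lists, the tests and the rule for naming genes were fixed. The pathway lists covered slow fibre, fast fibre, oxidative phosphorylation, tricarboxylic acid cycle, fatty acid oxidation, glycolysis and glycogen, lipid synthesis, regulators of mitochondrial biogenesis, immediate early, chaperone, atrophy and autophagy, clock, extracellular matrix, myogenesis, neuromuscular junction, calcium handling, antioxidant, interferon-induced, major histocompatibility complex, monoamine, myokine, insulin signalling, ribosomal protein and cell cycle genes. The cell type lists covered adipocytes, endothelial cells, smooth muscle cells and pericytes, fibroblasts, tendon, macrophages and monocytes, neutrophils, lymphocytes, mast cells, red blood cells, Schwann cells and nerve, and heart, liver and gut. Lists could share genes, such as Pvalb in fast fibre and calcium handling and Col1a1 in extracellular matrix and fibroblasts. The 35 lists with at least 4 genes tested were tested in SPORTS against WT with camera at a correlation of 0.01, adjusted over all lists. An estimated correlation and fry were alternatives. For comparisons of single arrays, a list's median was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. Counts "adjusted over the list alone" applied the adjustment within a list.

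Genes were named by fixed rules. For SPORTS against WT, the 10 largest rises and the 10 largest falls past the threshold were to be named, with places not filled going to genes with the largest gap between the pairs. For sedentary SPORTS against WT and for exercised against sedentary SPORTS, the 10 highest and the 10 lowest differences were named among genes whose difference exceeded 3 times that between the WT arrays and that were well above background where brighter. In each list up to 4 members with the largest difference were eligible. Maoa was named whatever its result.

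Alternatives were median scaling, quantile normalization, normexp background correction with an offset of 50 on the median signals, the authors' log2 values, no filter on dim genes, a filter on all 4 arrays, a floor at the lowest signal well above background, the mean of probes, a variance trend, a 1.5-fold threshold and leaving out each array. Each comparison was also tested on simulated data for 13326 genes, with 50 genes changed per size. In simulated data, the test of 2 arrays against 2 recovered 0 of 50 genes at a log2 change of 2 and 27 of 50 at 4, with 4 false calls over all sizes. Sedentary SPORTS against WT recovered 0 of 50 at a log2 change of 1, 32 at 2 and 46 at 4, with 9 false calls. Exercised SPORTS against WT recovered 40 of 50 at a log2 change of 2, and exercised against sedentary SPORTS 37 of 50. The simulation gave a gene the same spread on all 4 arrays. It could therefore not test whether lone SPORTS arrays vary like the WT pair. Only 200 genes were changed in each simulation, and the adjusted threshold loosens as more genes differ. The shares recovered therefore do not give the share these fits would recover in the data. Figures were drawn with matplotlib 3.10.9.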

Results

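Gene expression was measured in skeletal muscle of male rats aged 15 weeks, with 4 one-colour arrays. Sedentary WT Wistar muscle gave 2 arrays, an exercised SPORTS rat gave 1 array and a sedentary SPORTS rat gave 1 array. SPORTS is a hyperactive mutant rat whose background strain is Wistar. The labels name neither the muscle nor the kind of exercise. They also do not say whether the 2 WT arrays came from 2 animals, so the p-values measure only the spread between these samples, which may be technical. The titles of the WT arrays share their first number, unlike those of the SPORTS arrays, so both may come from 1 animal. The WT arrays differed by more than the noise between spots, so they are not 1 scan deposited again, which does not show that their RNA came from separate animals. Over 1002 probes with at least 3 spots, their difference had an SD of 0.11 on the log2 scale against 0.02 from the spots, and 51.9% of the probes lay outside the 95% range given by their own spots, where 5% would be expected.

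On WT arrays 1 and 2, 48.7% and 48.9% of the probes were well above background. The share was 46.0% on the exercised SPORTS array and 50.3% on the sedentary one. The median processed signal was 207 and 204 on the WT arrays, 138 on the exercised and 212 on the sedentary SPORTS array. The 100 brightest probes held 16.5% and 16.3% of the signal on the WT arrays, 18.3% on the exercised and 15.1% on the sedentary SPORTS array. The number of arrays limits the precision of every comparison. All 4 arrays shared 1 slide, so no batch could be compared.

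The exercised SPORTS array stood apart from the other 3. Of 13326 genes tested, 2920 differed at least 2-fold between the SPORTS arrays, 1214 higher and 1706 lower on the exercised one, and 1663 and 1354 with scaling by the median, which turns the excess round. Against WT arrays 1 and 2 the exercised array differed at least 2-fold for 2794 and 2747 genes, and the sedentary SPORTS array for 686 and 873. The WT arrays differed at least 2-fold from each other for 151 genes, or 1.13%.

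**Figure D1:**
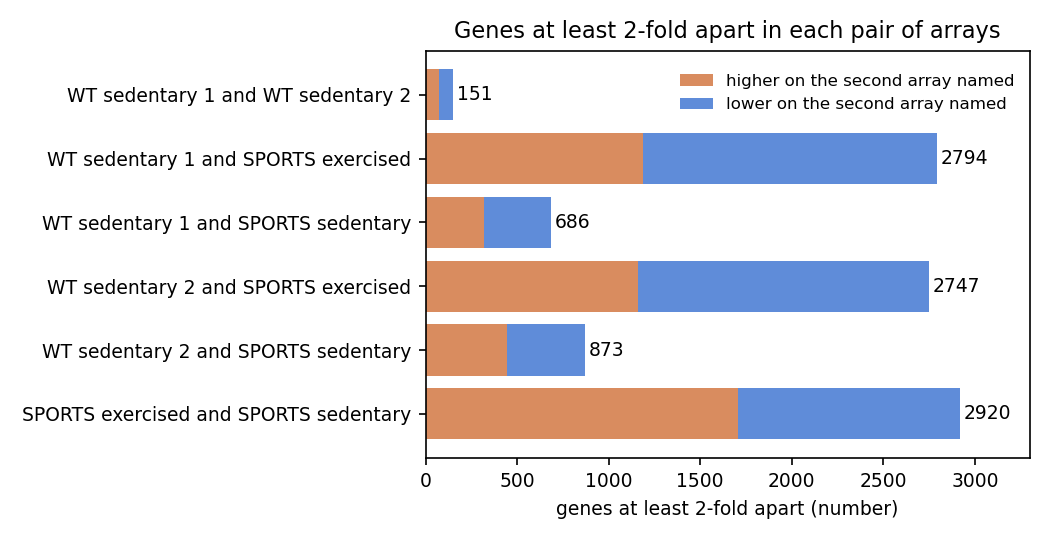
Horizontal bars give the number of genes, of 13326 tested, that differed at least 2-fold in each pair of the 4 arrays, divided by direction. The 3 pairs that hold the exercised SPORTS array have 2747 to 2920 genes and the WT pair has 151.

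The first comparison set both SPORTS arrays against both WT arrays, to ask which genes differ with genotype whether or not the animal exercised. Vegfb, which encodes a growth factor of the VEGF family, was at least 80.1-fold lower on the SPORTS arrays (adjusted p = 0.132, limma, n = 2 arrays per genotype). It has 1 probe, which was well above background on both WT arrays and on neither SPORTS array. Cd300lg, a receptor of the CD300 family, was at least 14.8-fold lower (adjusted p = 0.322), and the glucagon receptor gene Gcgr at least 4.80-fold lower. On the higher side, the core clock gene Bmal1 differed by 3.65 ± 0.43 on the log2 scale (adjusted p = 0.322). The Notch target Hes1 was at least 3.47-fold higher and the lipocalin gene Lcn2 at least 2.88-fold higher (adjusted p = 0.223 and 0.172).

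None of the 20 genes named for this comparison passed the adjusted threshold, and their places were filled by the size of the gap between the pairs. Among the others, Irgm, which encodes an interferon-induced GTPase, was at least 3.70-fold higher on the SPORTS arrays, and Oit3 was higher by at least 2.07 on the log2 scale. Lyst was at least 2.94-fold higher, Or13p4 at least 2.91-fold, the alpha globin gene Hba-a3 at least 2.89-fold and the nuclear receptor gene Nr4a3 at least 1.91-fold. Red blood cell markers, a list without Hba-a3, had a median of -0.50 over 6 genes, the other way, and were not called by camera. Ak1, an adenylate kinase gene, differed by 3.33 ± 0.67. On the lower side, Klkb1, encoding plasma kallikrein, was at least 3.17-fold lower. The retinoic acid binding protein gene Crabp1 was at least 4.65-fold lower, Wt1 at least 3.35-fold and the clock gene Ciart at least 1.99-fold. Pced1b differed by -3.22 ± 0.44, Mcrip1 by -3.03 ± 0.26 and Tpd52l1 by -3.03 ± 0.16. The 2 other probes of Wt1 were not above background on any array. The adjusted p of these 14 genes and of Gcgr ranged from 0.229 for Klkb1 to 0.551 for Oit3, except for 0.172 for Or13p4.

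Both SPORTS arrays lay at least 2-fold to one side of both WT arrays for 256 genes, 86 higher and 170 lower. The other 2 splits of the 4 arrays into pairs gave 27 and 33 such genes. Those splits set the WT arrays on opposite sides, so only the 151 genes at least 2-fold apart between the WT arrays could count. Their low counts follow from the closeness of the WT pair and do not give a chance level for the 256. limma called 0 genes in 2 arrays against 2, with 982 at an unadjusted p under 0.05 (452 higher and 530 lower) where 666.3 would be expected by chance. Quantile normalization and normexp background correction each called 1 gene, Vegfb. Without the exercised SPORTS array the test called 836 genes and the 2-fold count was 540. Without the sedentary SPORTS array the values were 7097 and 2481. The 2-fold count was 147 with normexp, 110 with genes well above background on all 4 arrays and 398 with no filter on dim genes. It includes values not well above background, and was 185 with these at the floor.

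Among the lists, those of clock genes and interferon-induced genes had the most members apart on both SPORTS arrays. Of 9 tendon markers, 5 lay at least 2-fold below both WT arrays by their measured values, a larger share than in either list. Of 27 interferon-induced genes, 6 lay at least 2-fold above both WT arrays and none below. Irf7, the transcription factor that drives interferon production, differed by 2.48 ± 0.30, the ubiquitin-like modifier gene Isg15 by 2.14 ± 0.29 and the antiviral GTPase gene Mx1 by 2.07 ± 0.38. None passed over all genes tested, and 7 did adjusted over the list alone. The list had a median of 0.43 and was called higher by camera (adjusted p = 1.12e-06, and 0.786 with an estimated correlation). Of 15 clock genes, 3 lay at least 2-fold above and 4 below both WT arrays by their measured values, though Ciart, among the 4, has a bound of only 1.99-fold. Bmal1, Nfil3 (2.88 ± 0.76) and Npas2 (2.01 ± 0.22) were higher, and Dbp differed by -2.83 ± 0.45, Per2 by -1.63 ± 0.16 and Tef by -1.46 ± 0.20. Npas2, Per2 and Tef were named to complete this count, after their values were seen. None passed over all genes tested and 8 did adjusted over the list alone. The second probe of Bmal1 was well above background on both SPORTS arrays and on neither WT array, and that of Npas2 differed by 0.17. As its members moved both ways, the clock list was not called (adjusted p = 0.441).

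Camera called 9 of the 35 lists, and each of the 9 had an adjusted p of 0.786 with an estimated correlation. Besides the interferon list, the glycolysis and glycogen list was called higher with a median of 0.65 (adjusted p = 0.0374), the immediate early list with 0.36 (0.00786) and the calcium handling list with 0.32 (0.0470). Called lower were fatty acid oxidation with a median of -0.60 (1.12e-06), the extracellular matrix with -0.76 (0.00483), lipid synthesis with -0.25 (0.00694), adipocyte markers with -1.14 (0.00432) and tendon markers with -2.96 (0.00432), a median that ranged from -3.01 to -1.09 over the settings. None of their members passed over all genes tested. Adjusted over the list alone, 2 immediate early genes, 1 lipid synthesis gene and 1 adipocyte gene did. The lipid synthesis gene Dgat2, which encodes an enzyme of triglyceride synthesis, differed by -2.49 ± 0.16 (adjusted p = 0.261). The fatty acid transporter gene Cd36 differed by -1.95 ± 0.39 and the second of its probes by -2.06. Fry called 2 lists, lipid synthesis and neutrophil markers (adjusted p = 0.0204 for both). The neutrophil list had 4 of 15 members measured, which went both ways, a median that ranged from -0.02 to 0.73 over the settings, and no call by camera (adjusted p = 0.202). In several of these lists 1 SPORTS array made most of the difference. The median of the glycolysis list was 1.56 on the exercised array against WT and -0.17 on the sedentary one. For calcium handling the medians were 0.72 and -0.06, and for adipocyte markers -2.21 and -0.12. That of the extracellular matrix list was -1.52 and 0.05, the latter from -0.10 to 0.08 over the settings. Other called lists lay on the same side of WT on both arrays, but unequally. In the same order, the medians were -0.89 and -0.22 for fatty acid oxidation, -4.55 and -1.35 for tendon and 0.20 and 0.67 for interferon-induced genes. They were -0.47 and -0.24 for lipid synthesis and 0.35 and 0.30 for immediate early genes.

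Maoa, encoding monoamine oxidase A, was named in advance because the strain has been studied for that enzyme. It differed between SPORTS and WT by 0.44 ± 0.28 (adjusted p = 0.768), and the sedentary array alone by 0.11 ± 0.06 (adjusted p = 0.309). On the exercised array Maoa rose by 0.77 ± 0.06 against WT (adjusted p = 0.00855, 3-group fit), without a second array to check it. Of 13 monoamine genes measured, none passed over all genes tested and 1 did adjusted over the list alone. The list was not called (adjusted p = 0.195).

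The second comparison set the sedentary SPORTS array against the WT arrays, taken as sedentary. It was meant to hold exercise equal, though the source names do not give the exercise state of the WT arrays. As the labels do not name the muscle, a different sampling site is not excluded here. Genes of fast fibres, the type II muscle fibres, were lower on the SPORTS array. Of 14 measured, 8 fell and none rose, with a list median of -1.20. The IIb myosin heavy chain gene Myh4 fell by 3.78 ± 0.21 on the log2 scale, the IIa myosin gene Myh2 by 3.64 ± 0.08, while the fast troponin gene Tnnt3 differed by -3.42 ± 0.11 and Tnni2 by -3.31 ± 0.07 (adjusted p = 0.0365 for Myh4 and 0.0319 for the others, limma). Adjusted over the list alone, 11 passed. Slow fibre genes had a median of -0.04, which ranged from -0.04 to 0.13 over the settings. Of 11, 2 rose: the phospholamban gene Pln by 1.12 ± 0.07 and the tropomyosin gene Tpm3 to 2.14-fold. A second Tpm3 probe, above background on 3 arrays, gave -0.44.

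Of 27 interferon-induced genes, 12 rose on the sedentary SPORTS array and none fell, with a median of 0.67. Irf7 rose by 2.83 ± 0.06, Mx1 by 2.51 ± 0.18 and Isg15 by 2.48 ± 0.10, and Irgm was at least 3.08-fold higher (adjusted p = 0.0319, 0.0391, 0.0322 and 0.0327). Of 15 clock genes, 3 rose and 6 fell. Bmal1 rose by 3.14 ± 0.19 and Npas2 by 2.21 ± 0.14, while Dbp fell by 2.27 ± 0.08 and Ciart was at least 2.25-fold lower. Adjusted over the list alone, 20 interferon-induced and 14 clock genes passed. Genes of the major histocompatibility complex had a median of 0.59, with 2 of 19 rising. Macrophage and monocyte markers had a median of 0.96, with none of 17 past the threshold, over all genes or over the list alone. The median of that list differed by -0.50 between the WT arrays.

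**Figure D2:**
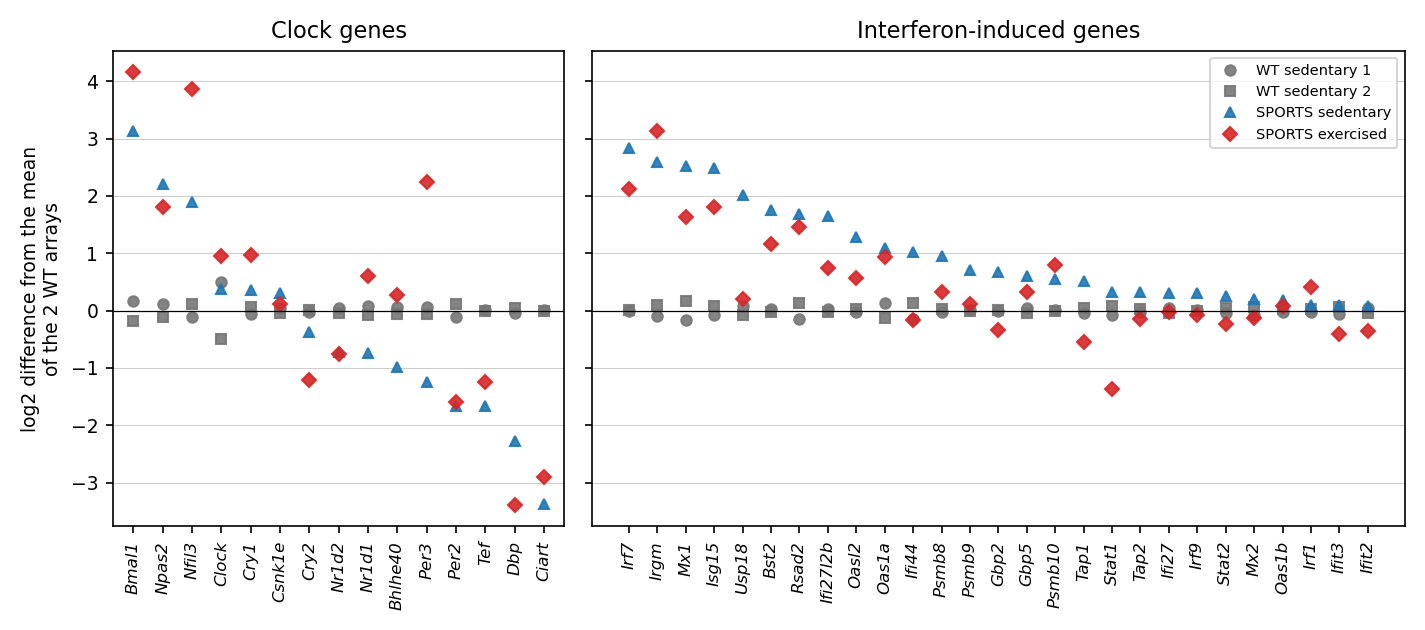
Points give the log2 difference of each array from the mean of the 2 WT arrays, for 15 clock genes and 27 interferon-induced genes in order of the sedentary SPORTS value. Bmal1 lies at 3.14 on the sedentary and 4.15 on the exercised SPORTS array, and Irf7 at 2.83 and 2.13. Bounds are not drawn, and Ciart, for example, was not well above background on either SPORTS array.

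Some genes of fatty acid oxidation and lipid synthesis fell on the sedentary SPORTS array. In fatty acid oxidation 7 of 32 genes fell and none rose, with a median of -0.22, among them Cd36 by 1.48 ± 0.10 and the lipid droplet gene Plin5 by 1.07 ± 0.07. In lipid synthesis 4 of 19 fell and 1 rose, with Dgat2 falling by 2.59 ± 0.09. Tendon markers had a median of -1.35, which was -0.02 with genes well above background on all 4 arrays, and 4 of 9 fell: Cilp2 by 1.80 ± 0.12, Chad by 1.72 ± 0.09, Fmod by 1.71 ± 0.09 and Tnmd by 1.46 ± 0.06. Glycolysis and glycogen genes had a median of -0.17, with 1 of 26 rising and 2 falling, the glycogen-associated phosphatase subunit gene Ppp1r3a by 1.51 ± 0.06 and Pfkfb1 2.82-fold.

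Among single genes, Vegfb was at least 90.7-fold lower, Cd300lg at least 16.8-fold, Gcgr at least 5.43-fold, Klkb1 at least 3.59-fold and Akr1b10 at least 2.53-fold. The water channel gene Aqp4 fell by 3.77 ± 0.12. The chemokine receptor gene Cxcr2 was at least 3.46-fold lower but missed the threshold (adjusted p = 0.0596). Hes1 was at least 3.97-fold higher, Lcn2 at least 3.08-fold, Or13p4 at least 2.79-fold, Hba-a3 at least 2.21-fold and Oit3 at least 1.86-fold. Lyst was at least 2.70-fold higher and missed the threshold (adjusted p = 0.0685). Hpd, a gene of tyrosine breakdown, rose by 2.91 ± 0.17 and the pyridoxal kinase gene Pdxk by 2.71 ± 0.09, each well above background on 1 of the 2 WT arrays. Apart from Cxcr2 and Lyst, the adjusted p of the 20 genes named ranged from 0.0277 to 0.0383.

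In all, 836 genes passed in sedentary SPORTS against WT, 376 higher and 460 lower. This count moved with the processing and was 0 with no filter on dim genes, 1611 with a floor on dim values, 2110 with normexp, 2170 with genes well above background on all 4 arrays and 2816 with a variance trend. The 3-group fit sets single SPORTS arrays against the spread of the WT pair, so its calls, here and below, compare these arrays and do not measure the spread between SPORTS rats.

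The third comparison set the exercised against the sedentary SPORTS array, which by their labels differ in exercise within the genotype. The labels do not name the muscle, so the arrays may also differ in sampling site, as weighed below. Each condition has 1 array, so the difference has no replicate check. Fast fibre genes were higher on the exercised array for all 14 measured, each at least 2-fold, with a list median of 3.32. Myh4 was 2331-fold higher, or 11.19 on the log2 scale. The fast actin-binding gene Actn3 was higher by 7.65, the calcium buffer gene Pvalb by 7.20 and the IIx myosin gene Myh1 by 6.49. Slow fibre genes were lower, 10 of 11 at least 2-fold, with a median of -2.31. The slow myosin light chain gene Myl2 had the largest difference of the list, followed by the myosin gene Myh7b at -3.45, the slow troponin gene Tnni1 at -3.40 and the cardiac and slow calsequestrin gene Casq2 at -3.36. Both medians lay at the ends of 10000 matched random lists, at percentiles 100 and 0. Between the WT arrays the medians were 0.07 for fast and -0.01 for slow fibre genes, at percentiles 99.8 and 22.2, so an extreme percentile also arose there.

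**Figure D3:**
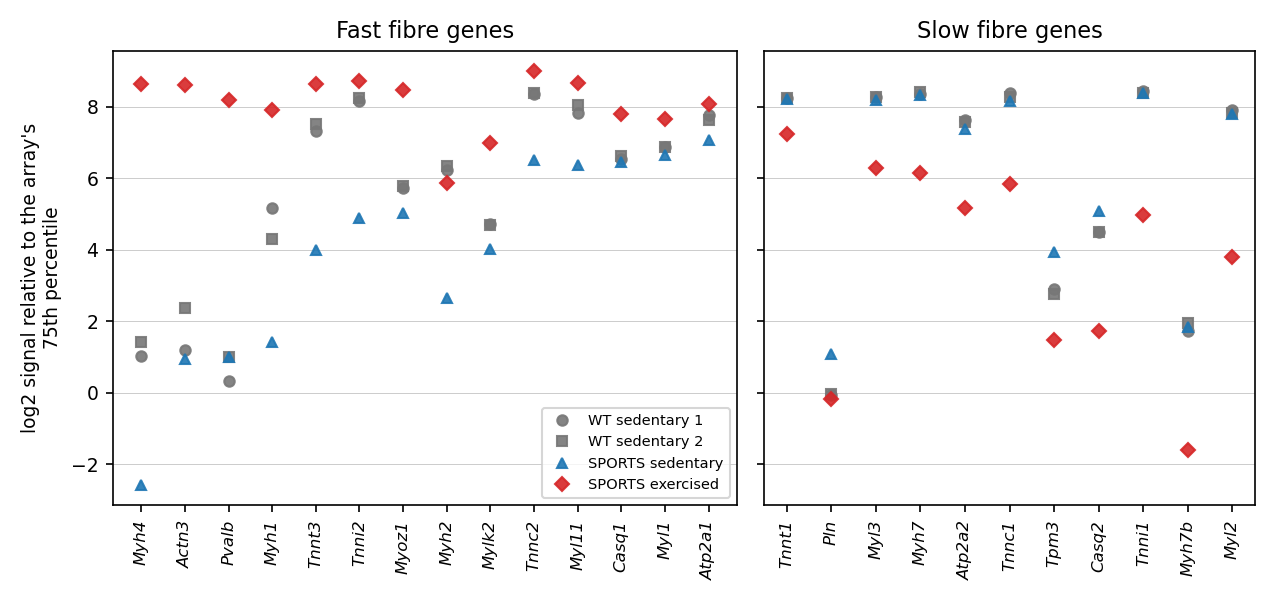
Points give the log2 signal of each array relative to its 75th percentile, for 14 fast fibre and 11 slow fibre genes in order of the difference between the SPORTS arrays. On the exercised SPORTS array Myh4 is 11.19 on the log2 scale above and Myh7b 3.45 below the sedentary one, while the 2 WT arrays lie close together for most genes.

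Glycolytic genes moved with the fast fibre genes. Of 26 glycolysis and glycogen genes, 20 were at least 2-fold higher and 1 lower on the exercised array, with a median of 1.91. The muscle fructose bisphosphatase gene Fbp2 differed by 4.99, the glycerol phosphate dehydrogenase gene Gpd1 by 4.14 and the phosphorylase kinase gene Phka1 by 3.11. Of 20 calcium handling genes, 6 were at least 2-fold higher and 1 lower, with a median of 0.81. The exception was Sln, encoding the calcium pump inhibitor sarcolipin, at -6.20. Among those higher were Atp2a1, Casq1 and Pvalb, which also belong to the fast fibre list, so the lists are not separate evidence. Fatty acid oxidation genes had a median of -0.75, with 10 of 32 at least 2-fold lower, among them the binding protein gene Fabp3 (-2.13) and the lipase gene Lpl (-2.11). In the same list 3 genes were at least 2-fold higher, including the uncoupling protein gene Ucp3 (3.24) and Pdk4 (2.23), which restrains pyruvate oxidation. Of 44 respiratory chain genes none differed at least 2-fold, and of 19 tricarboxylic acid cycle genes 1 was higher by that much, Idh3a (1.73), with members going both ways in each list. The medians were 0.01 and -0.05. Their sign changed with the scaling, from -0.29 to 0.20 and from -0.22 to 0.14.

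Markers of several other cell types were lower on the exercised array. All 17 macrophage and monocyte markers were at least 2-fold lower, with a median of -2.36, and Adgre1 was at least 4.41-fold lower. All 6 mast cell markers were at least 2-fold lower (median -1.95), as were 8 of 11 fibroblast markers (-1.57) and 7 of 10 adipocyte markers (-1.90). The adipocyte water channel gene Aqp7 differed by -4.57 and Cidea by -4.11. All 9 tendon markers were at least 2-fold lower by their measured values (median -2.74). Comp was at least 42.1-fold lower, Chad at least 19.1-fold and Tnmd at least 8.78-fold. Of 20 extracellular matrix genes, 15 were at least 2-fold lower (median -1.46), with Lum at -3.25 and Fn1 at -2.39. Some of these markers were not above background on the exercised array. With such values set to the lowest signal well above background, the medians were -2.34 for macrophage, -1.48 for mast cell (and -1.04 with normexp), -1.30 for fibroblast, -2.50 for tendon and -1.38 for matrix genes. Endothelial genes had a median of -0.18, which ranged from -0.18 to 0.01 over the settings. Smooth muscle and pericyte genes had a median of 0.11, from 0.04 to 0.30.

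Of the other genes named for this comparison, Mss51 was higher by 8.54, Cd24 by 6.39, the sodium pump subunit gene Atp1b2 by 5.62 and the lymphotoxin gene Ltb by 5.16. Lingo4 was at least 36.7-fold higher and Ifna5 at least 12.3-fold, each against a sedentary SPORTS array not well above background. The anion exchanger gene Slc4a3 differed by -6.03. Cda was at least 54.9-fold lower, Epn3 at least 36.3-fold, SPATA45 at least 14.4-fold, Rd3l at least 11.7-fold and Rrm2 at least 10.3-fold. The second probe of Rrm2 and that of Ifna5 were not above background on any array. That of Epn3 was above background on the sedentary SPORTS array alone.

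In the 3-group fit, 6699 genes passed between the SPORTS arrays, 3398 higher and 3301 lower, on the assumption that both lone arrays vary like the WT pair. Scaling by the median in place of the 75th percentile moved the median difference of all genes between the SPORTS arrays from 0.03 to 0.23 on the log2 scale. With it 5023 genes were higher and 2638 lower in that fit, and the 2-fold count was 1663 higher and 1354 lower. The 2-fold count was 4887 with no filter on dim genes and 5316 at a 1.5-fold threshold, where the WT pair gave 461. By their medians, 22 of 35 lists lay outside the central 95% of matched random lists between the SPORTS arrays, 19 between sedentary SPORTS and WT, and 15 between the WT arrays, with 1.75 expected by chance.

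The remaining comparison, exercised SPORTS against sedentary WT, differs by genotype and exercise together, and possibly by sampling site. Genes of fast fibres were again higher, with a median of 1.22, and those of slow fibres lower, with a median of -2.42. Pvalb rose by 7.52 ± 0.35, Myh4 by 7.40 ± 0.21 and Actn3 by 6.82 ± 0.61. Myl2 differed by -4.06 and Myh2 by -0.43. Glycolysis and glycogen genes had a median of 1.56, with Fbp2 rising by 5.45 ± 0.19. The tendon markers Chad and Comp were at least 62.9-fold and 50.3-fold lower. Of the clock and interferon genes named above, Bmal1 rose by 4.15 ± 0.19, Dbp fell by 3.39 ± 0.08, Irf7 rose by 2.13 ± 0.06 and Isg15 by 1.81 ± 0.10. Others did not follow the sedentary SPORTS array: Usp18 lay at 0.20 from WT here and at 2.01 there, and the used Per3 probe at 2.24 here and at -1.25 there. The median of the interferon list was 0.20, at percentile 93.1 of matched random lists, against 0.67 on the sedentary SPORTS array. Vegfb was at least 70.7-fold lower. The adjusted p of the genes given in this paragraph as risen, fallen or bounded ranged from 0.00424 to 0.00992. In all 7097 genes passed, 3634 higher and 3463 lower, and 5571 higher and 2505 lower with scaling by the median.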

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

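The tests of array brightness and of exercise below were chosen after the result was seen, and the test of positional genes before its result was seen. The 3 gene lists below were picked out because their medians lay at least 0.5 from WT on the log2 scale on both SPORTS arrays, in opposite directions, a difference that was not tested, as each condition has 1 array. The median of fast fibre genes differed by 3.32 between the SPORTS arrays, lying at -1.20 from WT on the sedentary and at 1.22 on the exercised array, with 13 of 14 members on each side. That of macrophage and monocyte markers differed by -2.36, from 0.96 on the sedentary array (16 of 17 members above WT) to -1.43 on the exercised one (17 of 17 below). That of mast cell markers differed by -1.95, from 0.52 (4 of 6 above) to -1.69 (6 of 6 below). With normexp the mast cell median on the sedentary array was 0.26, under the 0.5 needed. The macrophage and monocyte median differed by -0.50 between the WT arrays alone.

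The fibre pattern was weighed further, as it holds Myh4, the gene named with the highest difference between the SPORTS arrays (11.19). Brightness or scaling of the array is argued against by other corrections: under median scaling, quantile normalization and normexp the fast list stayed at 3.07 to 3.52 and the slow list at -2.63 to -2.11, with 2.11 as the smallest distance from 0. If the exercised array held another muscle, or another part of one, genes that mark position in the limb should differ too: the median absolute difference of 16 homeobox and T-box genes between the SPORTS arrays was 1.17, at percentile 99.94 of matched random lists, with 9 genes at least 2-fold apart, among them Emx2 (-3.06) and Hoxd9 (1.62), named after their values were seen. That is what another sampling site predicts. The same list reached percentile 97.6 between sedentary SPORTS and WT (0 genes at least 2-fold apart) and 84.0 between the WT arrays. Fast fibre genes differed between sedentary SPORTS and WT too (median -1.20), so that pair may also differ in sampling site and is no control. The percentile alone therefore does not settle the site. A response to exercise stays open and cannot be told apart from the sampling site, as there is 1 exercised array and the labels do not name the muscle.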

How the results depend on the processing

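Leaving out arrays for the count of genes apart by at least 2-fold, settings for the lists between the SPORTS arrays, and each WT array alone for named genes were chosen after seeing the data, and the other alternatives before. For SPORTS against WT, the count of called genes was 0 in 2 arrays against 2 and 1 with quantile normalization or normexp, and 0 to 7097 when 1 array was left out. The high end is the fit without the sedentary SPORTS array, in which the other SPORTS array stands alone against the WT pair. For sedentary SPORTS against WT, 836 became 2110 with normexp, 1611 with a floor and 2816 with a variance trend, where the cause was not tested. It became 0 with no filter on dim genes, with 26624 genes tested, and 2170 with the filter on all 4 arrays, with 11805 tested. The 256 genes apart by at least 2-fold became 147 with normexp (cause not tested), 398 with no filter, 110 with the filter on all 4 arrays, and 317 to 2481 when 1 array was left out, as fewer arrays need to lie apart: 350 and 317 without WT array 1 or 2, 540 and 2481 with a lone SPORTS array. The 2920 genes at least 2-fold apart between the SPORTS arrays became 4887 with no filter and 5316 at 1.5-fold, both of which admit more genes. The 9 lists called became 0 with an estimated correlation and 2 with fry, which tests another hypothesis. They numbered 8 to 13 under the other settings and 11 to 13 when 1 array was left out. The 7097 and 6699 genes of the comparisons with the exercised array stayed within 1.5 times under all alternatives run.

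For 61 results of named genes, 5 settings and each WT array alone were run. None reversed its direction, and under the 5 settings (normexp, quantile normalization, median scaling, the mean of probes and the authors' values) no call against WT was lost. With no filter on dim genes, under which 0 genes passed in sedentary SPORTS against WT, each of its calls was lost. With normexp 3 came past the threshold: Vegfb in SPORTS against WT (-6.20 on the log2 scale) and, in sedentary SPORTS against WT, Lyst (1.24) and Cxcr2 (-2.21). With quantile normalization Vegfb did (-8.41). Judged by value, as those between the SPORTS arrays were, results moved by more than the replicate spread for 16 with normexp, 15 with median scaling, 13 with quantile normalization, 4 with the mean of probes and none with the authors' values. Against each WT array alone, which gives no test, 14 results moved and 27 did not. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers. The slide was not run as a block, as there is 1 slide, and leaving out saturated genes removed none. Signal over background sets a limit on falls: where a gene was not well above background on one side, only a bound could be given.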

Other observations

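Between the SPORTS arrays, some genes of the nerve-muscle contact, of developing fibres and of proliferation differed by several fold, in both directions for the first 2 lists. Of 14 neuromuscular junction genes, 6 were at least 2-fold lower and 3 higher on the exercised array (median -0.55, from -0.55 to -0.11 over the settings): the fetal acetylcholine receptor subunit gene Chrng was at least 15.1-fold lower, the acetylcholinesterase anchor gene Colq at least 13.2-fold, and Chrnd differed by -3.89. Of 15 myogenesis genes, 7 were at least 2-fold lower and 3 higher (median -0.61, from -0.61 to -0.08), with the embryonic myosin gene Myh3 at -5.09, Actc1 at -3.20 and the satellite cell cadherin gene Cdh15 at 2.66. Cell cycle genes had a median of -1.08, -0.60 with values below background at a floor and -0.44 with genes well above background on all 4 arrays, where it lay at percentile 7.30, with Cdk1 at least 7.79-fold lower. Schwann cell and nerve genes had a median of -1.10 (7 of 12 at least 2-fold lower), from -1.10 to -0.67, and -0.82 with the floor. Against WT, the neurofilament gene Nefh was at least 2.67-fold lower on the sedentary SPORTS array (adjusted p = 0.0319, limma). Genes of the major histocompatibility complex had a median of -0.68, from -0.84 to -0.49 (8 of 19 at least 2-fold lower, class II genes RT1-Bb and RT1-Db1 at -2.60 and -2.51), and interferon-induced genes -0.51, from -0.55 to -0.31.

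Other lists differed less, or their members moved both ways, between the SPORTS arrays. Atrophy and autophagy genes had a median of 0.68, from 0.42 to 0.88 over the settings, with the muscle ubiquitin ligase genes Trim63 and Fbxo32 at 1.79 and 1.45, and insulin signalling genes 0.32, from 0.27 to 0.51. Myokine genes had a median of -0.89, from -1.02 to 0.43, with Il15 at 3.64 and Apln at -2.71. Immediate early genes had 0.14, from -0.09 to 0.33, with Ankrd1 at 4.93 and Ccn2 at -3.18. Lipid synthesis genes had 0.09, from -0.05 to 0.28, with Lpin1 at least 7.25-fold higher. Antioxidant genes had -0.31, from -0.37 to -0.12, with Gstm2 at 3.50 and Gsta3 at -2.99. Clock genes had 0.46, from 0.33 to 0.66, and red blood cell genes 0.43, from 0.34 to 0.63. Regulators of mitochondrial biogenesis had 0.20, from 0.08 to 0.40, monoamine genes 0.18, from 0.08 to 0.48, and neutrophil genes 0.38, from 0.08 to 0.58. Chaperone genes had 0.08, from -0.14 to 0.28, and ribosomal protein genes -0.03, from -0.40 to 0.16. Lymphocyte genes had -0.89, from -0.89 to 0.13, and in SPORTS against WT their median was -0.14 and their mean 0.06, with no call. Of the heart, liver and gut genes only Myh6 was measured, at -1.09, and with no filter on dim genes the median of the list was 0.44. In sedentary SPORTS against WT, red blood cell genes had a median of -0.73, with none of 6 past the threshold over all genes and 5 adjusted over the list alone. The used probe of the clock gene Per3 differed by 3.48 between the SPORTS arrays while a second was not well above background on the exercised array, where the used probe was brightest.

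In the following, the tests of fibre composition (both) and of genes with no other detected probe were chosen after the results were seen. The test of other probes was fixed before its result and limited to genes with such a probe afterwards. Several clock genes lay far from WT on both SPORTS arrays. Along the fast to slow axis, fibre composition went opposite ways (fast minus slow medians of -1.16 on the sedentary and 3.64 on the exercised array). All 5 genes in phase with Bmal1 lay above WT on both arrays. Of 7 genes opposite to it, 7 lay below WT on the sedentary and 5 on the exercised array. By their medians, the genes in phase were shifted above the opposite ones on both arrays. The shift had exact 95% lower bounds of 1.63 and 1.20 (1.30 and 1.20 with dim values at the floor) over genes, which are not independent replicates, and of 1.16 to 1.95 against each WT array alone, and this argues against that axis as the whole cause. A fibre type that differs the same way on both arrays stays open and cannot be told apart from the rest, as Myh2 lay at -3.64 and -0.43. Collection at another time of day predicts that genes in phase with Bmal1 and genes opposite to it part: their medians lay 3.56 apart on the sedentary, 3.06 on the exercised SPORTS array and -0.23 between the WT arrays, consistent with it. A clock that runs differently in the strain predicts the same 3.56, cannot be told apart from it, and the labels used here give no time of collection.

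The 256 genes apart between both genotypes could reflect sequence variants under single probes. For 22 genes with 24 other detected probes, these had a median difference of 1.89 in the direction of the first probe (95% bounds 1.40 to 2.28), or 1.68 with dim values at the floor (lower bound 0.82), and 18 of 24 were at least 2-fold, or 17 with the floor, which argues against variants under 1 probe as the main cause for these genes. For the 234 genes with no other detected probe, Vegfb among them, a probe variant cannot be told apart from a change in expression. Variants linked on a chromosome would place the genes near each other: 17 pairs lay within 5 measured genes, against a median of 16 in 10000 permutations (95th percentile 23), over 167 genes with a known place. That count neither shows nor excludes linkage, and a difference between the genotypes in expression stays open.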
